A study of Xenopus laevis with 24 samples.

How the data were processed

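RNA was measured by sequencing in 24 libraries of Xenopus laevis foregut tissue, the front part of the gut tube with its endoderm and the mesoderm around it. Per the labels' protocols, the tissue was cut out of embryos at Nieuwkoop and Faber stage 15 (NF15) and cultured at 15 °C until sibling stage NF25, NF33 or NF38. Each replicate pooled 8 explants, and the labels describe the 3 replicates of a condition as biological replicates. The labels name no parents of the embryos. The p-values below measure the spread between such pools. A difference in parents between groups would appear as a treatment difference, and this was not tested. Libraries were made with a stranded mRNA kit, per the labels' protocols. A setting of the counting step for strand is not given in the sources used here.

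The groups follow the sample titles. Controls carried a mismatch morpholino, an oligonucleotide with 5 exchanged bases, and were cultured in 0.1% DMSO. Loss of Rfx6 came from 2.5 ng of a translation-blocking morpholino injected at the 2-cell stage. Loss of retinoic acid signalling came from 250 nM BMS493, an inverse agonist of retinoic acid receptors, given right after dissection. The labels do not state whether explants in BMS493 also carried the mismatch oligonucleotide, or whether rfx6 morphants were kept in DMSO. There were 8 groups of 3: controls and rfx6 morphants at NF25, NF33 and NF38, and BMS493 explants at NF25 and NF33. A BMS493 group at NF38 was not analysed here.

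The authors deposited 1 table of estimated counts per gene and 1 table of TPM, which is expression scaled for transcript length and library total. The submitters' processing notes name RSEM 1.3.0 and Bowtie2 without saying what each did. The genome build and gene annotation are not given in the sources used here. The deposited counts are stored as whole numbers, and 6245 of 1067472 cells hold a count of 0 beside a TPM above 0, as rounded estimates would. Every column matched the library name in a sample's description. For rfx6 NF33 replicates 2 and 3, a further line of the description repeats the name of replicate 1, and the library name and title, which give replicates 2 and 3, were used. A row for reads without a gene identifier held 0% of the counts and was left out.

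The tables list 44478 genes by numbered identifiers (XBXL10_1g or XBmRNA followed by a number) and do not pair these with symbols. A RefSeq gene table for assembly Xenopus_laevis_v10.1 with 44456 genes was searched by gene number, locus tag, symbol, synonym, Ensembl and transcript or protein accession, and 0 of the identifiers matched. No gene is therefore named. The 29 gene lists fixed before the data were examined, the tests planned on them with camera and fry, the planned values of rfx6 and of retinoic acid response genes, and the planned sums over homeologous gene pairs were not run. Genes are described instead by their course over the 3 control stages. That grouping, the stage position below and the comparison of control NF38 with control NF25 were defined after the data had been seen. Xenopus laevis is allotetraploid, so near-identical gene copies may share reads, and the values of single identifiers carry that uncertainty.

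Counts, rounded to whole numbers where needed, were tested with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's filterByExpr with the 8 groups (minimum count 10, minimum total count 15), which left 28313 genes. Library sizes were scaled by TMM (trimmed mean of M-values). A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries (glmQLFit with robust estimates, glmQLFTest), and 12 contrasts were tested. Those were each treatment against its stage control (5), neighbouring control stages (2), BMS493 against rfx6 morphants (2) and the change of a treatment effect between stages (3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Genes that were also changed at least 2-fold are counted separately. Levels are CPM, counts scaled to a common library total, on the TMM scale, given as mean ± SD with n = 3 libraries. The labels' batch tag repeats the stage of culture, so stage and batch are confounded, while every comparison of a treatment with its stage control lies within 1 batch tag. The tests of a change in effect between stages run across batch tags.

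Stage position places each library on a scale where the control NF25 mean is 0 and the control NF38 mean is 100. It is the mean log2 CPM (prior count 2) of the 6767 genes at least 2-fold higher in NF38 than in NF25 controls, less that of the 4647 genes at least 2-fold lower. Its rising and falling parts use each set of genes alone, on the same scale. An error in library scaling shifts the parts in opposite directions and nearly cancels in the net value. Only the net value was recomputed under other scalings. Groups were compared by an exact two-sided permutation test of 3 against 3, whose smallest possible p is 0.1. The NF25 and NF38 controls thus chose these genes and also serve as the reference for the NF25 and NF38 treatment groups, so stage position at those stages is not independent of the choice of genes. For the stage groups, in contrast, a treatment effect was set against the control stage comparison that shares no library with it. For effects at NF25 that was control NF38 against NF33, for those at NF33 control NF38 against NF25, and for those at NF38 control NF33 against NF25. Shares in the stage groups are set beside all genes tested, which were not matched for level.

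Identifiers are printed by a rule set before the data were examined. It took, per treatment comparison, the called genes of largest absolute log2 fold change in each direction with an average log2 CPM of at least 1 and no overlap between treated and control libraries. The rule foresaw 8 names per direction and required a symbol. As no identifier has one here, the first 2 in each direction are given. Where every library of a group holds 0 counts, that group is set to a floor of 3 counts in all. The fold is then given as at least the resulting ratio. Where a group holds 1 to 3 counts in all, the ratio is given with its 95% exact (Clopper-Pearson) interval. Floors and intervals cover counting error only. A floor covers that of the group at 0 counts and takes the mean of the other group as exact.

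Library totals ran from 19433955 to 31005048 counts. The common biological coefficient of variation in the edgeR fit was 5.08%. In counts simulated from the real means and spread of all 28313 genes, with 200 genes changed in the rfx6 NF33 libraries, the edgeR fit of rfx6 morphants against controls at NF33 recovered 55.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 92.4% of those changed 4-fold. It called 0.0285% of the unchanged genes. The simulation held no stage effect and no other changed genes, so it does not test scaling where many genes change, as in the real libraries. No pair of replicates was a duplicate: over genes with at least 20 counts in a pair, the median squared difference was 1.70 to 3.59 times that of sampling noise.

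Alternatives set before the data were examined were DESeq2 1.42.0, DESeq2 size factors within edgeR, total library size without a composition factor, no filter on low counts, a filter at a mean of 1 CPM, a replicate block, a fit of the compared groups alone, counts thinned to the smallest library, limma 3.58.1 on log2(TPM + 1), a 2-fold threshold, and leaving out each library in turn. A fit without 9 repeat-like identifiers and a fit with another TMM reference library were added after the data had been seen. The repeat-like identifiers are those with a mean above 200 counts whose counts correlate over the 24 libraries at r above 0.95 with 1 identifier picked for its uneven counts between replicates. Figures were drawn with matplotlib 3.10.9.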

Results

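Gene expression was profiled in cultured foregut explants of Xenopus laevis to ask what is lost or gained when Rfx6 or retinoic acid signalling is removed, and how that changes over 3 stages. Rfx6 is an RFX-family transcription factor known from pancreatic and intestinal endocrine development, and retinoic acid is a vitamin A derivative that patterns the foregut through nuclear receptors. There were 24 libraries in 8 groups of 3, with 19433955 to 31005048 counts per library. Within a group, log2 CPM values of 2 libraries correlated across genes with r between 0.986 and 0.991, and between groups r ran from 0.764 to 0.976. Stage carried most of the variance, with 68.7% on the first principal component and 8.01% on the second. The files list genes by number without symbols, so rfx6 itself was not followed. A translation-blocking morpholino need not lower the RNA of its target.

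**Figure D1:**
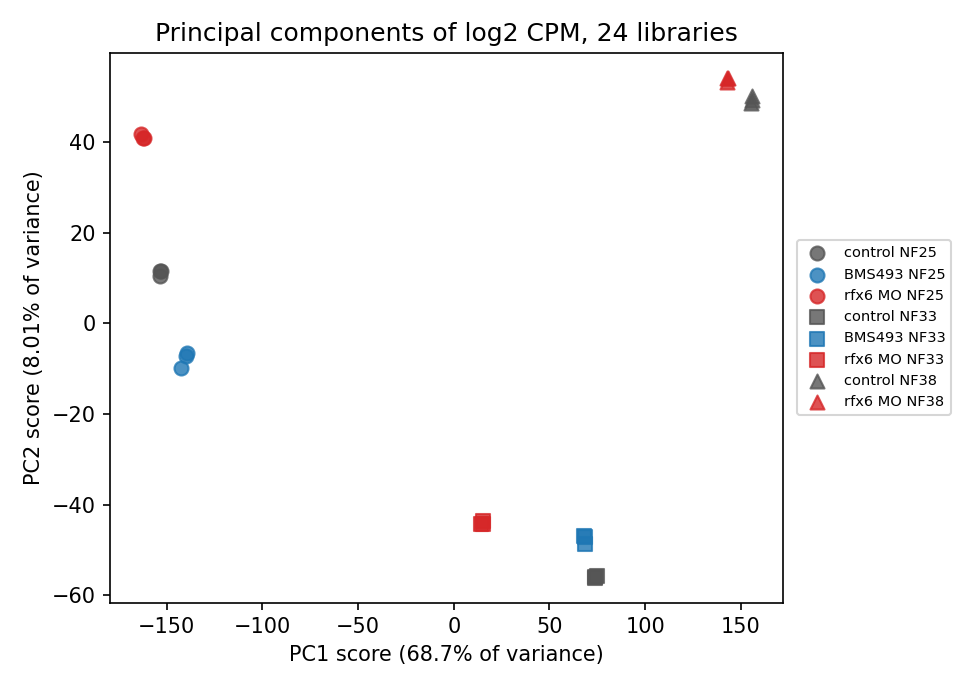
Scores of the 24 libraries on the first principal component (68.7% of variance, horizontal) and the second (8.01%, vertical), from log2 CPM of 28313 genes. Each point is 1 library, colours are treatments and shapes are stages; the 3 libraries of each group lie together and the rfx6 morphants at NF33 sit between the NF25 and NF33 controls on the first component.

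Control explants gave the course of normal development. From NF25 to NF33, 9131 genes changed at least 2-fold, of which 5359 rose and 3772 fell. From NF33 to NF38, 4780 genes changed at least 2-fold, 2984 up and 1796 down. The group that rose at least 2-fold in both steps held 1324 genes, and 735 fell in both. A rise followed by a fall was seen for 316 genes and a fall followed by a rise for 421. Over the whole interval from NF25 to NF38, 6767 genes rose and 4647 fell at least 2-fold. At the adjusted p threshold alone, edgeR's quasi-likelihood test called 20082 genes between NF25 and NF33 and 15362 between NF33 and NF38. Whether more of such calls were higher or lower depended on the settings: in all 12 comparisons tested, the majority turned under at least 1 other setting. Among genes changed at least 2-fold it turned in 1 of the 5 treatment comparisons, BMS493 at NF25. The labels' batch tag follows the stage, so these differences cannot be separated from batch. Stage groups and stage position, which are built on them, carry the same limit.

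In rfx6 morphants at NF25, the earliest stage, 1988 genes differed at least 2-fold from controls, 1228 higher and 760 lower. The higher genes stood low in controls, with a median of 0.499 CPM against 2.15 CPM in morphants. Together they took 18512 ± 231 CPM in morphants and 6007 ± 56.8 CPM in controls (SD, n = 3). Of these 1228 genes, 422 (34.4%) belonged to those that rise at least 2-fold from NF33 to NF38 in controls, a group that makes up 10.5% of all genes tested (odds ratio 5.01). Among the 760 lower genes the same group held 126 (16.6%). Genes that fall over that step, 6.34% of all genes, made up 137 (11.2%) of the higher and 92 (12.1%) of the lower genes. In total 514 of the 1988 genes (25.9%) had moved toward the later stage, 263 (13.2%) toward the earlier one, and 1211 (60.9%) did not change 2-fold between these control stages. Of the 1228 higher genes, 798 stood under 1 CPM in NF25 controls. Genes that low may have passed the filter through a later group. Part of the excess of genes that rise later may come from that, as all genes tested are no background matched for level. Stage position was -0.749 ± 0.132 in morphants against 0 ± 0.115 in controls (SD, n = 3; exact permutation p = 0.1, the smallest possible). Its parts moved in opposite directions, with the rising genes at 5.04 ± 0.303 and the falling genes at -8.17 ± 0.153, so the net value is smaller than either part. An error in library scaling would also move the parts in opposite directions. The net difference was not stable: it was -0.0997, -0.433 and -0.0311 without control NF25 replicate 1, 2 and 3 in turn. Each of these fits also chose the stage genes anew, so the values do not single out 1 library.

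Among single genes at NF25, XBXL10_1g12510 stood at 0.530 ± 0.0747 CPM in rfx6 morphants and at 0 counts in all 3 control libraries, at least 11.1-fold higher (edgeR adjusted p = 3.76e-08). XBXL10_1g8357 stood at 4.41 ± 0.388 CPM against 0.0487 ± 0.0470 CPM, a ratio of 92.4 with a 95% counting interval of 31.3 to 450. In the other direction, XBXL10_1g37728 fell from 0.212 ± 0.0916 CPM to 0 counts, at least 4.92-fold lower (edgeR adjusted p = 5.99e-04). XBXL10_1g31103 fell from 6.69 ± 0.704 to 0.583 ± 0.473 CPM, a log2 fold change of -3.46 (SE 0.18; edgeR adjusted p = 7.34e-21). In all, 9798 genes passed the threshold, 5100 higher and 4698 lower. Their balance depended on scaling, with 3378 higher and 7163 lower under total library size and 3244 higher and 5637 lower for limma on log2(TPM + 1).

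**Figure D2:**
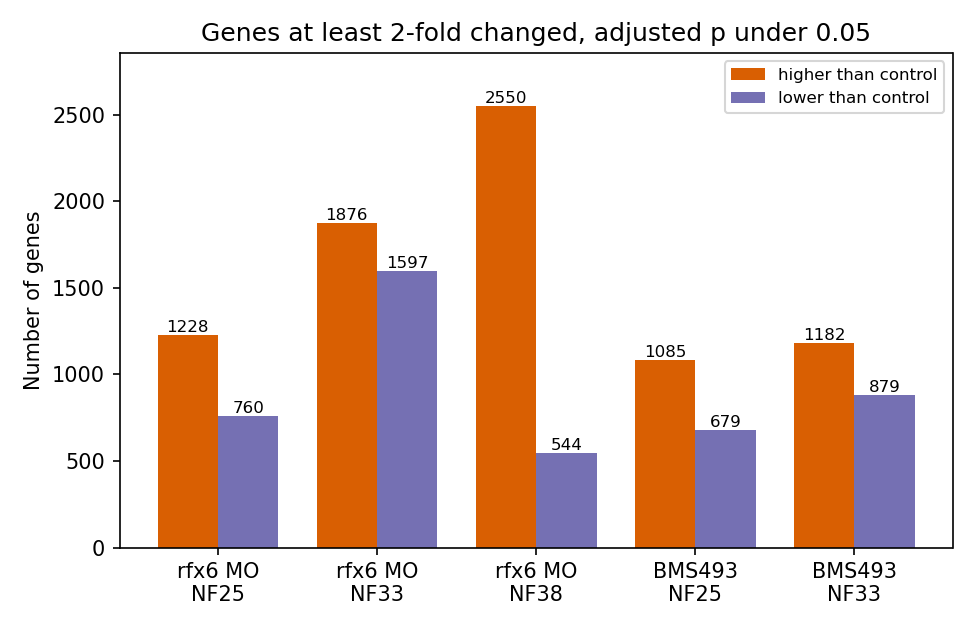
Number of genes (vertical) with an adjusted p under 0.05 and a change of at least 2-fold in each of the 5 treatment comparisons (horizontal; rfx6 MO is rfx6 morpholino), split into higher and lower than the stage control. At NF38 the rfx6 morphants had 2550 higher and 544 lower genes.

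At NF33 most genes that were lower in rfx6 morphants were genes that rise between the control stages. Of the 1597 genes at least 2-fold lower in morphants, 1359 (85.1%) were genes that rise from NF25 to NF38 in controls, against 23.9% of all genes tested (odds ratio 22.5). Of the 1876 genes at least 2-fold higher, 855 (45.6%) were genes that fall over that interval, against 16.4% of all genes (odds ratio 5.00). In total 2214 of the 3473 genes (63.7%) had moved toward the earlier stage, 497 (14.3%) toward the later one, and 762 (21.9%) did not change 2-fold between these control stages. The median log2 fold change was -0.33 over all 6767 rising genes and 0.54 over all 4647 falling genes. Genes are not independent replicates, so these shares are descriptions and carry no p-value.

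Stage position summarised the same rising and falling genes in the same libraries, now per library, and is no second test of the shift. Control NF33 libraries lay at 68.7 ± 0.321 on the scale from NF25 (0) to NF38 (100), and rfx6 NF33 libraries at 49.6 ± 0.364 (SD, n = 3; exact permutation p = 0.1, the smallest possible). The difference of -19.1 points was far larger than either SD. Its parts were unequal: the rising genes stood at 54.5 ± 0.483 against 67.6 ± 0.192 in controls, and the falling genes at 43.3 ± 0.390 against 70.1 ± 0.539. The lower genes together fell from 41897 ± 550 CPM in controls to 13541 ± 415 CPM in morphants. Beyond the shift, 313 genes stood at least 2-fold above every control stage and 89 at least 2-fold below every control stage, 11.6% of the 3473.

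**Figure D3:**
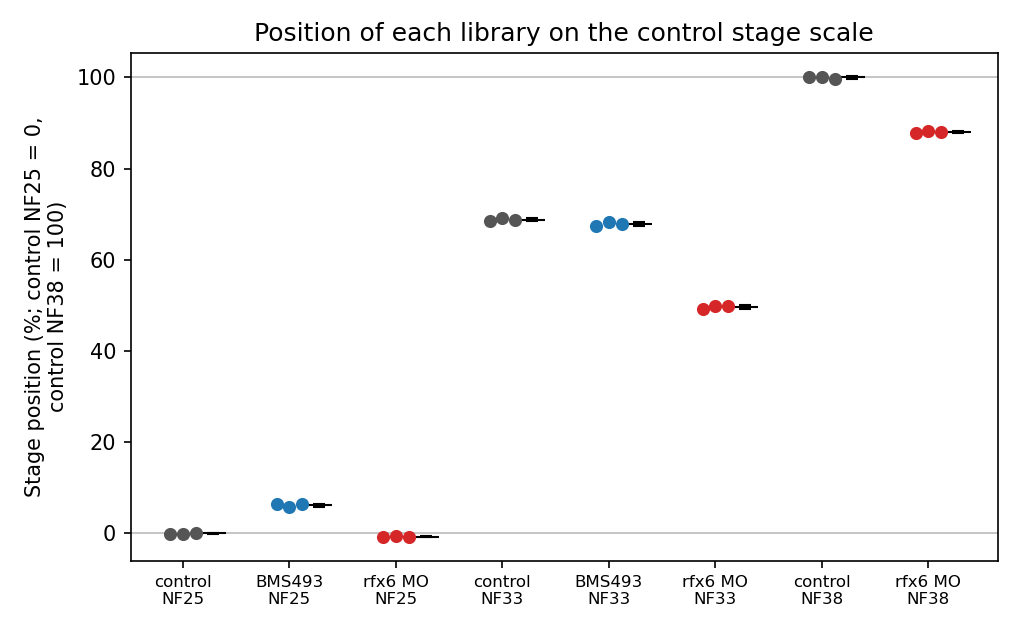
Stage position of each library (vertical, percent of the way from the control NF25 mean to the control NF38 mean) in the 8 groups (horizontal). Points are single libraries, and the black marks beside them are the group mean and SD of 3 libraries. The rfx6 morphants lie at 49.6 at NF33 and at 88.1 at NF38, below the controls at 68.7 and 100.

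XBXL10_1g42198 rose at NF33 from 0.307 ± 0.146 CPM in controls to 458 ± 1.60 CPM in morphants, a log2 fold change of 10.52 (SE 0.11; edgeR adjusted p = 1.35e-53). It was also at 184 ± 11.5 CPM in morphants at NF25 and at 69.7 ± 6.16 CPM at NF38, against 6.38 ± 0.994 and 9.89 ± 0.664 CPM in the controls. XBXL10_1g19313 stood at 10.8 ± 0.273 CPM in NF33 morphants and at 0 counts in controls, at least 293-fold higher, and was at 7.73 ± 0.613 and 8.21 ± 0.285 CPM in morphants at NF25 and NF38. XBXL10_1g6849 fell from 4.71 ± 0.237 CPM to 0 counts, at least 129-fold lower. In controls this gene reached 349 ± 8.61 CPM by NF38, and in morphants 208 ± 15.8 CPM. XBXL10_1g13397 fell from 2.34 ± 0.407 CPM to 0 counts, at least 64.2-fold lower, and stood at 87.2 ± 3.41 CPM in controls and 38.0 ± 3.59 CPM in morphants at NF38. The 14080 genes called at NF33 comprised 7207 higher and 6873 lower; limma on log2(TPM + 1) gave 7744 and 4401, and DESeq2 size factors 6861 and 7311.

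At NF38 most of the genes changed at least 2-fold in rfx6 morphants were higher. Of 3094 genes at least 2-fold changed, 2550 (82.4%) were higher and 544 lower. The higher genes took 75176 ± 1560 CPM in morphants against 28914 ± 261 CPM in controls (SD, n = 3), and 1043 of them stood under 1 CPM in controls. Of the 2550, 972 (38.1%) were genes that fall from NF25 to NF33 in controls, against 13.3% of all genes (odds ratio 5.05). Of the 544 lower genes, 262 (48.2%) were genes that rise over that step, against 18.9% (odds ratio 4.13). In total 1234 of the 3094 genes (39.9%) had moved toward the earlier stage, 526 toward the later one, and 1334 (43.1%) did not change 2-fold between these control stages. Stage position was 88.1 ± 0.207 (exact permutation p = 0.1, n = 3, the smallest possible), and its parts differed: the rising genes alone gave 100.3 ± 0.0791 and the falling genes alone 72.4 ± 0.531. An error in library scaling would shift these parts in opposite directions, and the scale at this stage depended on the TMM reference library. Their SD does not cover that, so the level of either part is uncertain.

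The genes lower in morphants at NF33 were closer to controls at NF38. Of the 1597 genes at least 2-fold lower at NF33, 736 (46.1%) were not called at NF38, 701 (233 of them at least 2-fold) were called lower, and 160 were called higher. Their median log2 fold change was -1.66 at NF33 and -0.36 at NF38, and the test of the difference between stages called a weaker or opposite effect for 1164 (72.9%). For the 1876 higher genes the median went from 1.64 to 0.90, and that test called 723 (38.5%). Part of this decline is inherent in choosing genes by their NF33 value. Calls at NF38 and for the difference between stages also depend on the TMM reference library. These shares were not recomputed with another one.

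XBXL10_1g17973 was at 22.5 ± 0.726 CPM in NF38 morphants and at 1 count over the 3 control libraries, a ratio of 1913 with a 95% counting interval of 343 to 75594. XBXL10_1g20751 stood at 10.7 ± 0.632 CPM, again against 1 count in controls, a ratio of 910 (interval 163 to 35982). XBXL10_1g18472 fell from 20.6 ± 0.703 to 2.07 ± 0.485 CPM, a log2 fold change of -3.32 (SE 0.16; edgeR adjusted p = 1.72e-28). XBXL10_1g28740 fell from 13.9 ± 0.373 to 1.40 ± 0.239 CPM, a log2 fold change of -3.31 (SE 0.19; edgeR adjusted p = 1.24e-24). At the adjusted p threshold alone 13344 genes were called, 7203 higher and 6141 lower. This balance turned with the reference library of the TMM scaling: another reference, tried after the data had been seen, gave 5913 higher and 8370 lower, and 2185 against 709 among genes at least 2-fold changed. It also turned without any 1 of 5 of the 6 libraries (control NF38 replicates 1 and 3 and each rfx6 NF38 replicate), to between 5703 and 5883 higher and between 6843 and 7193 lower.

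Across stages, part of the rfx6 effect recurred. At least 2-fold changes in the same direction were shared by 585 genes between NF25 and NF33, by 999 between NF33 and NF38 and by 334 between NF25 and NF38. Independent lists would share 124.2, 199.6 and 125.2. Changes in opposite directions numbered 149, 80 and 81, against 119.6, 179.9 and 92.0 for independent lists. At all 3 stages 180 genes were higher (7.33 by chance) and 37 lower (0.824 by chance).

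Tests of a difference in effect between stages run across batch tags, so they cannot separate stage from batch. The test of the difference in rfx6 effect between NF33 and NF25 called 9541 genes, 5274 with a higher and 4267 with a lower log2 fold change at NF33. Total library size gave 7497 and 2780, with the median log2 difference of all genes at 0.168 in place of 0.0406, and limma on log2(TPM + 1) gave 7442 and 2860. DESeq2 size factors turned the majority, with 4312 higher and 5039 lower, as did DESeq2 with 4196 and 5011. Between NF38 and NF33, 8774 genes differed, 5276 higher and 3498 lower. That split was 3971 against 5656 with another TMM reference and 2898 against 5262 with limma on log2(TPM + 1). It was 4096 against 4116 without control NF38 replicate 3, 4336 against 4371 without rfx6 NF33 replicate 1 and 4171 against 4495 without rfx6 NF38 replicate 1.

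BMS493 at NF25 changed 1764 genes at least 2-fold, 1085 higher and 679 lower, while limma on log2(TPM + 1) gave 210 higher and 230 lower. The 1764 genes showed little direction along the stage course: 295 (16.7%) had moved toward the earlier stage, 305 (17.3%) toward the later one, and 1164 (66.0%) did not change 2-fold between the NF33 and NF38 controls. The 679 lower genes fell together from 9823 ± 76.6 CPM to 3137 ± 31.4 CPM (SD, n = 3). Stage position was 6.16 ± 0.369 (exact permutation p = 0.1, n = 3, the smallest possible), with 8.65 ± 0.912 for the rising genes and 2.97 ± 0.344 for the falling genes. XBXL10_1g41015 stood at 1.55 ± 0.209 CPM and at 0 counts in controls, at least 32.5-fold higher. XBXL10_1g12510, also higher in rfx6 morphants at this stage, was at 0.541 ± 0.106 CPM, at least 11.3-fold higher. XBXL10_1g25775 fell from 0.823 ± 0.125 CPM to 0 counts, at least 20.8-fold lower. XBXL10_1g41471 fell from 1.07 ± 0.384 CPM to 1 count over 3 libraries, a ratio of 79.6 with a 95% interval of 13.8 to 3191. Of 8737 genes called, 4559 were higher and 4178 lower; total library size gave 3608 and 5164, and limma on log2(TPM + 1) 3148 and 4346.

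At NF33, BMS493 changed 2061 genes at least 2-fold, 1182 higher and 879 lower. These moved along the stage course in both directions, 810 (39.3%) toward the earlier stage and 710 (34.4%) toward the later one, and 541 (26.2%) did not change 2-fold between these control stages. Genes that rise from NF25 to NF38 in controls made up 591 of the 1182 higher and 554 of the 879 lower genes, against 23.9% of all genes. Genes that fall over that interval, 16.4% of all genes, made up 256 (21.7%) of the higher and 119 (13.5%) of the lower genes. Stage position was 67.8 ± 0.381, a difference of -0.896 points from controls (exact permutation p = 0.1, n = 3, the smallest possible). Its parts moved apart, with the rising genes at 68.3 ± 0.297 against 67.6 ± 0.192 in controls and the falling genes at 67.2 ± 1.21 against 70.1 ± 0.539. An error in library scaling would also part them. A larger part than in rfx6 morphants lay outside the control course: 265 genes stood at least 2-fold above and 132 at least 2-fold below every control stage, 19.3% of 2061. No test compared these shares.

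XBXL10_1g41186 stood at 28.5 ± 1.05 CPM in BMS493 explants at NF33 and at 0 counts in the controls, at least 773-fold higher. XBXL10_1g41188 stood at 25.9 ± 2.64 CPM, at least 701-fold higher. In controls both were present by NF38, at 9.88 ± 0.278 and 11.9 ± 0.960 CPM. In rfx6 morphants they stood at 4.06 ± 0.256 and 3.16 ± 1.05 CPM at NF33, and at 28.7 ± 3.00 and 24.7 ± 2.61 CPM at NF38. XBXL10_1g20797 fell from 1.69 ± 0.541 CPM to 0 counts, at least 45.5-fold lower. Rfx6 morphants at NF33 held it at 0.103 ± 0.123 CPM. XBXL10_1g28961 fell from 6.32 ± 0.137 to 0.0752 ± 0.0405 CPM, a log2 fold change of -6.32 (SE 0.28, edgeR adjusted p = 3.82e-31). It was at 5.92 ± 0.152 CPM in NF33 morphants. At NF25 it was at 0.914 ± 0.336 CPM in BMS493 explants against 18.7 ± 0.784 CPM in controls. Of 8209 genes called, 3610 were higher and 4599 lower. The majority turned with another TMM reference (4133 higher, 4049 lower), with no filter on low counts (4109 and 4067) and without BMS493 NF33 replicate 3 (3573 and 3432).

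Between the BMS493 stages, 393 genes were changed at least 2-fold in the same direction (66.4 for independent lists) and 56 in opposite directions (62.0). The test of the difference in BMS493 effect between NF33 and NF25 called 7475 genes, 3279 with a higher and 4196 with a lower log2 fold change at NF33. Total library size gave 4120 and 3171, and limma on log2(TPM + 1) 3720 and 2910.

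**Figure D4:**
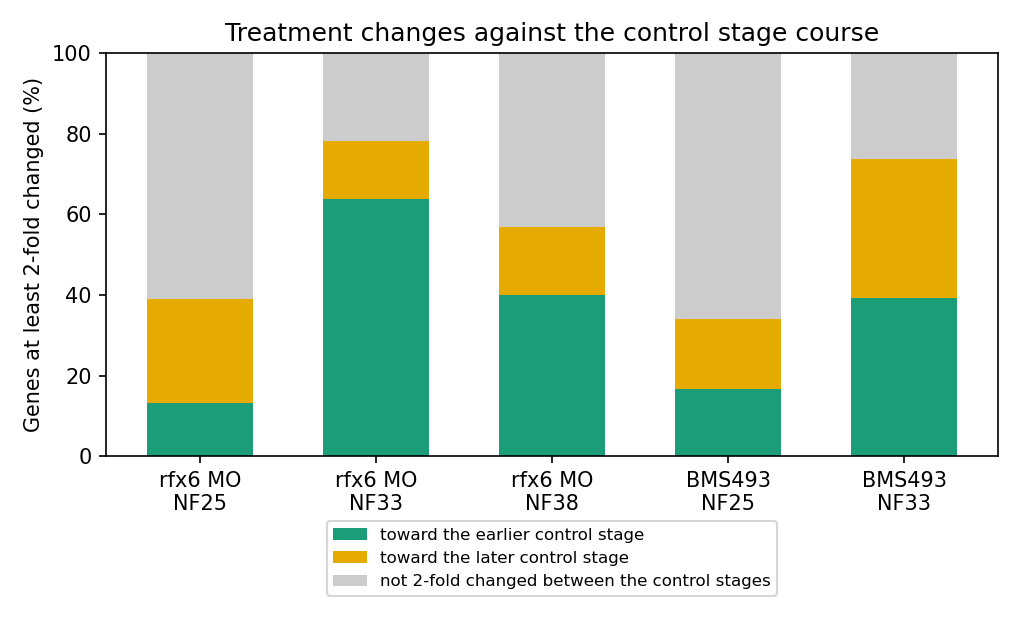
Percent of the genes at least 2-fold changed in each treatment comparison (vertical) that moved toward the earlier control stage, toward the later one, or did not change 2-fold between these control stages, taken from controls that share no library with the comparison. For rfx6 morphants at NF33, 63.7% moved toward the earlier stage and 14.3% toward the later one.

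Many genes changed in the same direction under both treatments at NF33. Those changed at least 2-fold in both numbered 1181, with 700 higher and 481 lower in both, and 34 changed in opposite directions. Independent lists would share 78.3 higher and 49.6 lower genes and hold 124.9 in opposite directions. Simulated unchanged groups with shared controls had 0.1 such genes in common on average, but only 1.2 and 2.5 calls to begin with, too few to measure what shared controls add to lists of this length. Of the 481 genes lower in both, 418 (86.9%) rise from NF25 to NF38 in controls, as do 941 of the 1116 (84.3%) lower at 2-fold in morphants alone. Of the 398 genes lower at 2-fold with BMS493 alone, 136 (34.2%) do. Of the 700 higher in both, 305 (43.6%) rise in controls and 196 fall. The 1176 genes higher at 2-fold in morphants but not with BMS493 included 659 (56.0%) that fall in controls. At NF25 the overlap was smaller, with 301 higher and 154 lower in both and 75 in opposite directions, against 47.1, 18.2 and 58.6 for independent lists; the simulation gave 0.2 in the same direction, from 2.6 and 2.0 calls.

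Across all genes, log2 fold changes of the treatments correlated with r = 0.60 at NF33 and 0.375 at NF25, where the simulated unchanged groups with shared controls gave 0.502 and 0.529. The covariance was 0.501 at NF33 and 0.261 at NF25, against 0.0586 and 0.0893 in the simulation. That leaves 0.442 and 0.172. With 3 control libraries per stage the controls were not divided between the treatments, so part of the overlap may come from sharing them. The labels name the mismatch morpholino and DMSO for the controls only. An effect of either that both treated groups lack would appear as a shared change, and this was not tested.

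Compared directly, BMS493 explants and rfx6 morphants differed at least 2-fold in 2987 genes at NF25, 1452 higher with BMS493 and 1535 lower. At NF33 they differed in 2993 genes, 1454 higher and 1539 lower. The adjusted p threshold alone called 12204 genes at NF25 and 13181 at NF33, the latter 6379 higher and 6802 lower, or 4241 and 7095 with limma on log2(TPM + 1) and 6958 and 6252 with DESeq2 size factors. Without BMS493 NF33 replicate 2 or 3 or any 1 rfx6 NF33 replicate, between 6179 and 6333 were higher and between 5681 and 5872 lower.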

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

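Planned before the data were examined were the 3 tests of a difference between stages and, as alternatives, DESeq2 size factors, total library size, the filter at a mean of 1 CPM and the fits without 1 library. The bound for the count of genes outside all control stages was set before its result was known, and the other tests, as well as the use of those alternatives to weigh a pattern, were chosen after the results they bear on had been seen.

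The effect of each treatment differed between stages for many genes. Stage follows the batch tag, so a response that differs between batches would give the same calls. By edgeR's test of the difference, 9541 genes differed in their response to the rfx6 morpholino between NF33 and NF25, 8774 between NF38 and NF33, and 7475 in their response to BMS493 between NF33 and NF25. Other splits of the same 12 libraries, exchanging labels within a stage, were refitted on those libraries alone, in a random draw of 60 per test that includes the real one. For the rfx6 effect at NF33 against NF25, the real split gave 9700 calls and the highest of the others 5718, with 1 of 60 splits as large. For BMS493, the real split gave 7323 and the highest of the others 2086, again 1 of 60. For the rfx6 effect at NF38 against NF33, the real split gave 9603 and 2 of 60 splits were as large. The highest other, 16653, exchanged all control and morphant labels at 1 stage, which turns the difference of the effects into their sum. The next highest was 5754. That kind of split was not among those drawn for the other tests. Fitted separately, it also exceeded the real split, with 13634 calls for rfx6 at NF33 against NF25 and 9015 for BMS493. All remaining splits mix treated and control libraries in at least 1 stage. Where a treatment acts, such mixing widens the spread within groups and lowers the calls by construction. Fewer calls in those splits therefore cannot decide whether the effect differs between stages. The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05, and in each of the 9 the real split alone (1) called genes, from 7764 to 20173, with 0 in the highest other.

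Single identifiers were among these, with 17 of the 24 differences looked at passing the test (largest edgeR adjusted p 0.0385). The log2 difference in rfx6 effect between NF33 and NF25 was -7.09 for XBXL10_1g12510, -7.25 for XBXL10_1g8357, 5.36 for XBXL10_1g37728, 1.87 for XBXL10_1g31103, 5.84 for XBXL10_1g19313 and 5.68 for XBXL10_1g42198. Between NF38 and NF33 it was -7.71 for XBXL10_1g42198, 9.19 for XBXL10_1g6849, 7.74 for XBXL10_1g13397, 8.74 for XBXL10_1g17973, 9.35 for XBXL10_1g20751 and -3.80 for XBXL10_1g18472. For BMS493 between NF33 and NF25 it was -7.95 for XBXL10_1g41015, -6.66 for XBXL10_1g12510, 6.44 for XBXL10_1g25775, 5.699 for XBXL10_1g41471 and -1.99 for XBXL10_1g28961. The identifiers were picked for extreme values at 1 stage, which favours a difference from the other stage. Where a group stands at 0 counts, the fitted value depends on the prior count and is no bound. Groups at 0 counts at NF25 also left standard errors too large for a test between NF33 and NF25. This held for XBXL10_1g6849 and XBXL10_1g13397 with rfx6, and for XBXL10_1g41186, XBXL10_1g41188 and XBXL10_1g20797 with BMS493. These differences did not pass, but they are undecided rather than absent.

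The first pattern weighed is the shift of rfx6 morphants at NF33 toward the earlier stage. Library scaling as its cause is argued against by the share of genes that moved toward the earlier stage, which was at least 63.0% under 4 other scalings. A swapped or mislabelled library is argued against by stage position, where the rfx6 NF33 libraries lay at least 17.5 points from any library of another group, against a largest SD of 0.381 within a group. Younger explants as the whole cause stay open. In the rfx6 groups of all 3 stages, 46 genes (43 above, 3 below) stood at least 2-fold outside all control stages. That was short of the more than 50 set beforehand as the bound for excluding this cause. None of the control stages analysed gave the levels of these 46 genes. Levels outside the control course cannot decide, however, whether age accounts for the shift along it. Earlier harvest and slower progression of the same explants cannot be told apart either, since the only measure of age is the stage position of 49.6, whose rising and falling parts (54.5 and 43.3) differ, with no control between NF25 and NF33 analysed here to show whether age alone would part them, and a delay of development without Rfx6 is therefore a hypothesis these data could fit but do not separate from a difference in age.

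The next pattern is the excess of higher genes in rfx6 morphants at NF38, 82.4% of those at least 2-fold changed. Library scaling as the whole cause is argued against by a lowest share of 75.5% over 4 other scalings, although the balance of all 13344 calls did turn with the TMM reference library and without any 1 of 5 of the 6 libraries (5703 to 5883 higher). Low counts are argued against by a share of 86.5% among genes with a mean of at least 1 CPM. Other cells in the explants stay open: 40.9% of the higher genes stood under 1 CPM in controls, but with no identifier matched to a marker gene, extra cells and a change within the same cells cannot be told apart.

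The last pattern is the presence of XBXL10_1g17973 and XBXL10_1g20751, at 529 ± 43.3 and 70.7 ± 7.14 CPM in NF25 controls and under 0.1 CPM in later controls, in rfx6 morphants at NF38 (22.5 and 10.7 CPM) and in BMS493 explants at NF33 (84.3 ± 2.45 and 21.5 ± 2.03 CPM). A single deviating library is argued against, as the lowest library held 89.9% of its group's mean. RNA of NF25 explants mixed into these libraries would leave other NF25 transcripts at the same percent of their NF25 level, but over 12 genes that lose nearly all of it in later controls the median was 0.689% in rfx6 NF38, against 3.02% and 3.997% for the identifiers, and 1.79% in BMS493 NF33, against 24.2% and 33.4%. A first version of this test, on 3 genes, gave medians of 3.02% and 24.2%, as mixing would, and was replaced after that had been seen because 2 of the 3 genes were these identifiers, so that the median was the value of 1 of them; the 12 genes include both as well. Different parents of the explants stay open: 3 genes stood at 20 CPM or more in all NF25 groups and under 0.5 CPM in later controls, and as the labels name no parents, parents and treatment cannot be told apart.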

How the results depend on the processing

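The fit without 9 repeat-like identifiers and the fit with another TMM reference library were chosen after the data had been seen, and so was stage position as a measure; all other alternatives were planned. No named identifier changed direction or lost its call under any alternative that gave it a value. Counts of calls stayed within 1.5 times the reported count in 164 planned cases and not in 21, in all 38 added after the data had been seen, and in all 138 that left out 1 library. What moved were counts under 3 settings, some differences in stage position, and, with limma on log2(TPM + 1), the shares at NF25 of genes that moved toward the earlier stage, to 5.75% for rfx6 morphants and 8.86% for BMS493.

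A 2-fold threshold gives fewer calls by construction: rfx6 morphants 1988, 3473 and 3094 at NF25, NF33 and NF38, BMS493 1764 and 2061 at NF25 and NF33, control stages 9131 and 4780, BMS493 against rfx6 morphants 2987 and 2993, differences between stages 2639 and 2548 for rfx6 and 2175 for BMS493, and overlaps of the treatments 455 at NF25 and 1181 at NF33. A filter at a mean of 1 CPM tests fewer genes (22888) and gave 2205 genes at least 2-fold changed in rfx6 morphants and 1276 with BMS493 at NF33. With limma on log2(TPM + 1), whose pseudocount shrinks the fold of low genes, these were 643, 1175 and 1075 in rfx6 morphants at NF25, NF33 and NF38, and 440 (210 higher and 230 lower) and 671 with BMS493 at NF25 and NF33.

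Replicate numbers did not pair the samples: 0 of 21 same-numbered pairs deviated together at r above 0.1, and 7 of 24 libraries correlated best with their own number. With the number as a replicate block, the calls for rfx6 morphants were 9662, 13872 and 13155, and no call count moved by over 1.5 times.

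At the adjusted p threshold, the majority of higher or lower calls turned under at least 1 setting in 12 of 12 comparisons. Without the repeat-like identifiers, edgeR picked another TMM reference library, and that choice alone gave nearly the same split at NF38 (5913 higher and 8370 lower, against 5914 and 8369). Over all 24 possible references the rfx6 NF38 scale shifted by -0.0923 to 0 on the log2 scale, with the reported fit at the end of that range. Small fold changes in either direction at that stage are therefore within the uncertainty of scaling.

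The difference in stage position of rfx6 morphants at NF25 ran from -1.40 to -0.0311 over the alternatives, at NF33 from -19.5 to -18.9 and at NF38 from -12.7 to -11.9. Sums over homeologous genes, the gene list tests with preset or estimated correlation, and the symbol part of the rule for naming genes were not run.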

Other observations

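The tests described in this part were chosen after the data had been seen.

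A small group of genes stood outside the range of the controls in rfx6 morphants at every stage: 43 stood at least 2-fold above and 3 at least 2-fold below each of the 3 control stages in each of the 3 morphant groups. XBXL10_1g19313, at 7.73, 10.8 and 8.21 CPM in morphants at NF25, NF33 and NF38, stood at 0.190, 0 and 0.0227 CPM in the controls. XBXL10_1g31103 rose in controls from 6.69 ± 0.704 CPM at NF25 to 1518 ± 24.5 CPM at NF33 and 4683 ± 83.1 CPM at NF38. In morphants it reached 504 ± 9.16 CPM at NF33 and 4051 ± 209 CPM at NF38, and in BMS493 explants 1125 ± 7.57 CPM at NF33.

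Genes past 2-fold with BMS493 alone at NF33 were set against their course in controls. Of the 482 genes higher with BMS493 but not in morphants, 286 (59.3%) rise from NF25 to NF38 in controls. A gene past 2-fold under 1 treatment and not under the other is not thereby shown to differ between them, and no test compared this share with others.

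The 9 repeat-like identifiers were chosen for matching 1 identifier with uneven counts between replicates. That their counts match and vary between replicates follows from this choice. They took from 1.35% of all counts in the lowest library to 9.77% in rfx6 NF25 replicate 2, and 9.16% in BMS493 NF25 replicate 3. For 6 of them the counts equalled those of another identifier in all 24 libraries, with 4 in the largest identical set. Group means were 4.94 ± 1.42% in NF25 controls, 2.86 ± 0.569% in NF33 controls and 2.08 ± 0.0780% in NF38 controls (SD, n = 3). No explanation was tested.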
